A study of Rattus norvegicus with 6 samples.

How the data were processed

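Small RNA libraries were made from 1 μg of total RNA each with a ligation-based kit for small RNA and sequenced as single-end reads of 50 bp, per the labels' protocols. The labels give 3 HO-1 knockout and 3 wild type libraries from rat testicle, all collected 3 days after torsion of 720° for 2 h, and each of the 6 value columns was matched to its sample by name, with 0 unmatched sample columns. The labels do not say that equal replicate numbers mark a shared litter, batch or day. They do not state that each library came from a separate animal, so p-values measure only the spread between these libraries.

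The authors deposited 1 table with reads per 1000000 assigned reads (RPM) for 764 rat miRNA entries, rounded to 2 decimals, in which each library sums to that total. It also holds the authors' mean RPM of each genotype, their log2 fold change and their p-value, per the file headers. The deposited log2 fold change equals the log2 ratio of the deposited means within 5e-05 for the 501 miRNAs with both means above 0. Whether the deposited p-value was adjusted for multiple tests, and by which test it was made, is not given in the sources used here. FastQC, BWA, edgeR and the rat build rn6 are named in the submitters' processing notes, with no role, order or version. Trimming, mismatch rules, the miRNA annotation release and the treatment of reads that match several miRNAs are not given in the sources used here. Among rows of at least 10 RPM, let-7a-1-3p and let-7c-2-3p, and miR-466b-2-3p and miR-466b-4-3p, had identical values in every library, so the members of each pair cannot be told apart here. The same holds for a mature sequence with several genomic copies, such as miR-92a-3p.

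The design fixed before the data were examined assumed a table of counts and named a test on log2(RPM + 1) in limma for the case that only normalized values were held. Since the table holds RPM, limma was the main test. limma with an intensity trend was fitted to log2(RPM + 1) of the 570 miRNAs with a value above 0 in some library, with genotype as the only factor and no further filter, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 194 rows at 0 in every library were not tested. Shares of reads and library totals were compared by exact two-sided permutation tests of 3 against 3 libraries, whose smallest p is 0.1.

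The RPM values fall on whole multiples of 1 step per library, so reads were recovered from them. Of the values above 0, between 97.8% and 98.9% lay within 0.0051 RPM of a whole number of reads, against 9.3% to 10.9% by chance, and the recovered reads of each library summed exactly to its recovered total. The step of wild type library 1, 0.0996 RPM, lies so close to 0.1 that low values alone do not separate it from rounding, and its total rests on the higher values. Totals were 8300536 to 10042673 reads, so 3 reads, used as the limit that a count of 0 allows, equal 0.299 to 0.361 RPM per library. PCR copies were not removed, so such limits cover counting error only. Count tests on recovered reads were run only as alternatives.

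Before the data were examined, 19 lists of miRNAs were fixed. They covered the miR-221/222 cluster, the miR-34 and miR-449 family, the X-linked testis cluster, miR-202, the miR-290 cluster, the miR-17-92 clusters, the cluster of miR-183, miR-96 and miR-182, let-7, leukocyte, red blood cell, endothelial, stromal and striated muscle markers, miR-29, the miR-200 family, markers of other organs, miR-210, injury-induced miRNAs and the imprinted Dlk1-Dio3 cluster. The injury list shares 12 of its 25 rows with other lists. The 17 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists, with an estimated correlation and with fry as alternatives. fry asks whether a list's members move one way on balance, not whether they differ from other miRNAs.

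The rule for named miRNAs was also fixed beforehand. It takes every arm of miR-221 and miR-222, up to 12 rising and 12 falling miRNAs with the smallest adjusted p below 0.05, the 10 most abundant, and up to 4 of the most abundant members of each list. Of the uncalled list members, mostly the 2 most abundant are named. This narrowing was chosen after the data were seen, when many uncalled members had changed sign between settings, and it left out 21 members that the rule allows. miR-34b-5p, miR-96-5p and miR-200c-3p were kept to complete their families. Others named as called members of a list, or for a single value, were chosen after their values were seen. Precursors were grouped by neighbourhood from a RefSeq gene table on GRCr8, in which 532 of the 570 tested miRNAs had a precursor. That table's assembly differs from rn6, so its coordinates are not printed.

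Alternatives fixed beforehand were TMM, RLE and upper-quartile scaling, a mean of at least 10 RPM, pseudocounts of 0.1 and 5, totals without the 10 most abundant miRNAs, the replicate number as a block, a fold of at least 2, DESeq2, limma-voom and edgeR's exact test on recovered reads, and leaving out each library. edgeR's quasi-likelihood test, totals without miR-122-5p and a mean of at least 1 RPM were added after the data were seen. The planned settings of no filter and of library totals alone coincide with the main test. The recovery of reads, the limma and count tests and the set tests were tested on simulated data for this comparison, and the permutation tests and random draws were not. Whole reads were recovered for 100.0% of simulated counts of 764 miRNAs. In 570 simulated miRNAs of which 200 were changed, limma recovered 27% of those with a 2-fold change and 48% of those with a 4-fold change. Among those of at least 10 RPM it recovered 69% and 100%. Of all its calls, 1.3% were unchanged miRNAs. As many simulated miRNAs rose as fell, and the 10 most abundant were left unchanged. These rates therefore do not cover errors from a shift in the share of an abundant miRNA such as miR-122-5p. Simulated miRNAs were drawn independently of each other, so the set tests were not checked on lists with correlated members. In the data the estimated correlation was 0.41 for the miR-221/222 list, 0.46 for the stromal list and 0.52 for the miR-183 cluster. The software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.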

Results

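Small RNA was sequenced from rat tissue labelled testicle, 3 days after a testicular torsion of 720° that lasted 2 h. The 6 libraries came from male Sprague Dawley rats, 3 of them HO-1 knockout and 3 wild type. HO-1 is heme oxygenase 1, the stress-inducible enzyme that breaks heme down into biliverdin, iron and carbon monoxide. All 6 libraries followed the same injury, so the only contrast was between genotypes, and no sham or uninjured library was analysed here. The messenger RNA of HO-1 was not measured by this assay, so the knockout labels could not be checked against the deleted gene. Values were reads per 1000000 assigned reads (RPM) over 764 rat miRNA entries, of which 570 had a value above 0 in some library. The size of 1 read in each library gave totals of 10042673, 9128924 and 9477412 reads for wild type libraries 1 to 3 and 8300536, 9809055 and 8991102 reads for knockout libraries 1 to 3. Totals averaged 9549670 ± 461140 reads in the wild type and 9033564 ± 755155 reads in the knockout (SD, n = 3; exact two-sided permutation p = 0.4, with 0.1 the smallest possible).

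The libraries labelled testis were dominated by miR-122-5p, a miRNA known from hepatocytes, in both genotypes. It held 35.2% ± 2.2 of the reads in the wild type and 43.4% ± 3.1 in the knockout (SD, n = 3), with every library between 32.7% and 46.4%. The next most abundant miRNAs were miR-148a-3p, at 113404 ± 8466 RPM in the wild type and 94559 ± 10972 RPM in the knockout, and miR-21-5p, an injury-associated miRNA, at 70161 ± 2243 and 77665 ± 2604 RPM. They were followed by let-7f-5p, miR-192-5p, miR-26a-5p, let-7g-5p, let-7a-5p, the endothelial miR-126a-3p and miR-99a-5p. miRNAs of germ cells and Sertoli cells were far less abundant. miR-34c-5p, of meiotic and postmeiotic germ cells, stood at 30.7 ± 6.7 RPM in the wild type and 20.5 ± 1.8 RPM in the knockout, miR-34b-5p at 6.43 ± 1.85 and 4.62 ± 0.59 RPM, and the gonadal miR-202-5p at 1.23 ± 0.34 and 1.3 ± 0.81 RPM. No member of the X-linked testis cluster passed 3.59 RPM in any library, a value reached by miR-547-3p. None of the tested rows of these 3 testis lists, 8 of the miR-34 and miR-449 family, 15 of the X-linked cluster and 1 of miR-202, changed with genotype in limma's test, either over all miRNAs or adjusted over the list alone. Summed over 39 testis rows, chosen after the data were seen, values were 48.5 ± 8.3 RPM in the wild type and 32.7 ± 2.9 RPM in the knockout, lower in all 3 knockout libraries than in any wild type library (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible).

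The higher share of miR-122-5p in the knockout had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. The 10 most abundant miRNAs together held 79.3% ± 1.5 of the reads in the wild type and 82.6% ± 1.2 in the knockout (SD, n = 3; exact p = 0.1). Among 22 shares compared in this way, the Benjamini-Hochberg adjusted p was 0.14 for both.

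**Figure D1:**
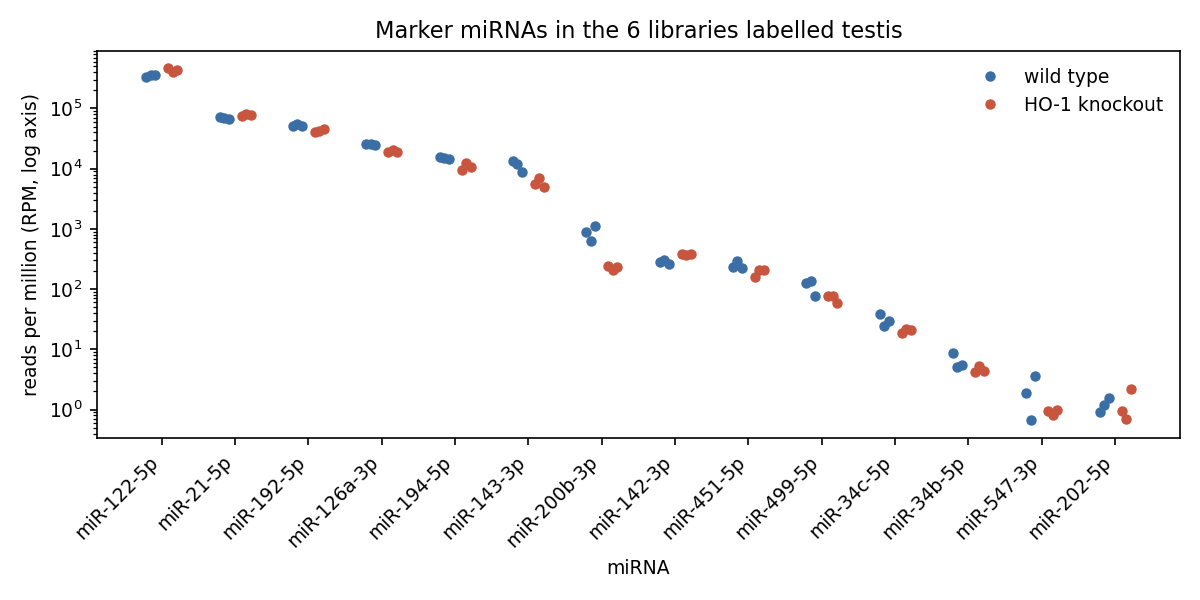
RPM of 14 marker miRNAs on a log axis, with 1 point for each of the 3 wild type and 3 HO-1 knockout libraries. miR-122-5p lies at or above 326912 RPM in all 6 libraries, while miR-547-3p and miR-202-5p stay at or under 3.59 RPM.

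Between genotypes, 36 of the 570 tested miRNAs changed, of which 32 fell and 4 rose in the knockout (limma, Benjamini-Hochberg adjusted p below 0.05). The 12 falling miRNAs with the smallest adjusted p were miR-31a-5p, miR-200b-3p, miR-221-3p, miR-20a-5p, miR-100-5p, miR-125b-5p, miR-200a-3p, miR-126a-5p, miR-30a-5p, miR-200b-5p, miR-143-5p and miR-16-5p. miR-31a-5p fell from 1416 ± 87 to 597 ± 79 RPM (SD, n = 3), a log2 change of -1.25 (SE 0.12, limma adjusted p = 0.0033), and miR-200b-3p, of the epithelial miR-200 family, from 881 ± 251 to 224 ± 16 RPM, a log2 change of -1.93 (SE 0.21, limma adjusted p = 0.0033). The 4 that rose were miR-375-3p, a miRNA of endocrine cells, from 44.4 ± 9.6 to 110.8 ± 12.4 RPM, miR-29b-3p, a regulator of collagen genes, from 79.2 ± 7.9 to 150.2 ± 17.2 RPM, miR-674-3p from 89.1 ± 11.7 to 156.0 ± 17.5 RPM, and miR-196b-5p from 0.87 ± 0.26 to 3.58 ± 0.58 RPM. Their log2 changes were 1.32 (SE 0.19), 0.91 (SE 0.15), 0.80 (SE 0.15) and 1.29 (SE 0.22), with limma adjusted p of 0.015, 0.016, 0.023 and 0.017.

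These fold changes are on the scale of log2(RPM + 1), relative to the total of each library, and understate changes of rare miRNAs. The 218 miRNAs of at least 10 RPM had a median log2 change of -0.29. TMM scaling moved that median by 0.21, to -0.08, and gave 49 calls, 20 higher and 29 lower, of which 31 were among the 36. On whole reads recovered from the RPM steps, edgeR's quasi-likelihood test called 62 miRNAs, 29 higher and 33 lower, with 32 of the 36 among them. The number of calls fell to 17 without wild type library 2, and to 13, 21 and 5 without knockout libraries 1, 2 and 3. miR-31a-5p, miR-200b-3p, miR-221-3p and miR-20a-5p remained called with any single library left out. Among the fits with 1 library left out, miR-100-5p, miR-125b-5p, miR-200a-3p, miR-30a-5p and miR-375-3p were lost in 1, that without knockout library 3 (limma adjusted p between 0.071 and 0.079), and the other 27 calls in 2 or more. miR-30a-5p was also lost with RLE and with upper-quartile scaling.

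**Figure D2:**
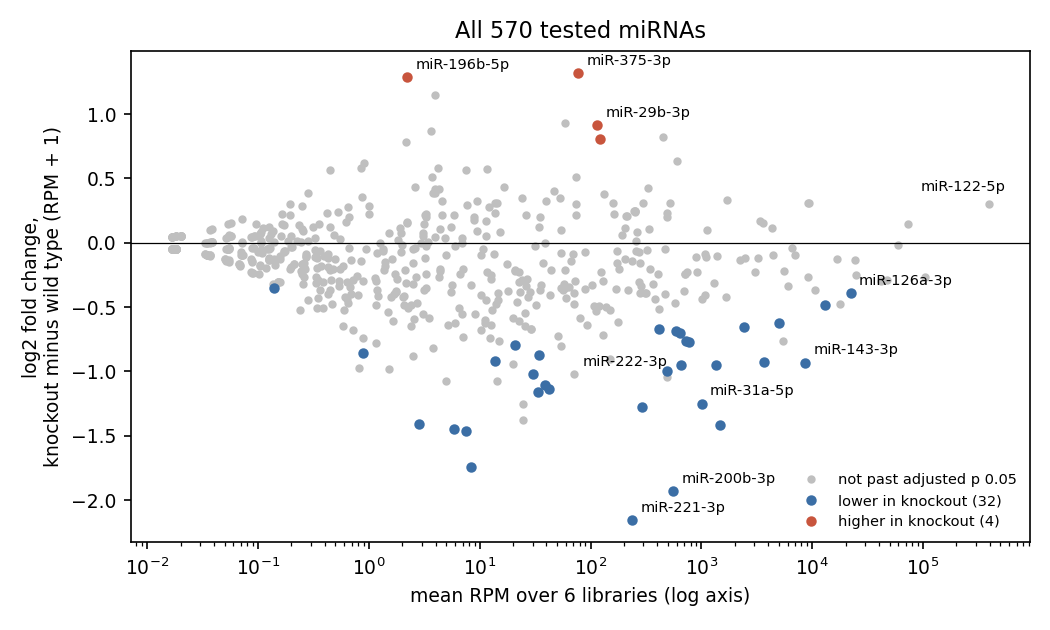
Log2 fold change of each of 570 miRNAs, HO-1 knockout minus wild type on log2(RPM + 1), against its mean RPM over the 6 libraries on a log axis. Blue points are the 32 miRNAs called lower, red points the 4 called higher, and grey points did not pass an adjusted p of 0.05 in limma.

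The series title names a pathway from HO-1 through phosphorylated c-Jun to miR-221 and miR-222, and TOX. This pair of miRNAs is transcribed from 1 cluster on the X chromosome. Phosphorylated c-Jun and TOX were not measured by this assay. In every library used here miR-122-5p held at least 32.7% of the reads, so which tissue these values describe is not settled. All 3 arms of the cluster that passed the test were lower in the knockout. miR-221-3p fell from 391 ± 135 RPM in the wild type to 83.9 ± 6.9 RPM in the knockout (SD, n = 3), 4.66-fold lower, with a log2 change of -2.16 (SE 0.23, limma adjusted p = 0.0033). Its values were 540, 279 and 354 RPM in wild type libraries 1 to 3 and 76.3, 89.5 and 86.0 RPM in knockout libraries 1 to 3. The other strand, miR-221-5p, fell from 13.6 ± 5.3 to 3.19 ± 0.47 RPM, with a log2 change of -1.74 (SE 0.31, limma adjusted p = 0.021).

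miR-222-3p stood at 96.6 ± 36.4 RPM in the wild type and 45.03 ± 0.47 RPM in the knockout, a log2 change of -1.02 (SE 0.25) that missed the threshold over all miRNAs (limma adjusted p = 0.056). On the recovered reads it passed, with an adjusted p of 0.023 in edgeR's quasi-likelihood test and a log2 change of -0.87. With TMM, RLE and upper-quartile scaling of the RPM it missed (limma adjusted p between 0.057 and 0.096). miR-222-5p was close to the limit of detection (limma adjusted p = 0.047). It had 8 reads over the 3 wild type libraries and 0 over the 3 knockout libraries. With 3 reads over the group in place of that 0, it would be 2.52-fold lower. This figure leaves out the counting error of the 8 reads, so it is not a lower limit of the fold. Adjusted over the list alone, 4 of the 4 arms passed. The study may have chosen this list on these samples. Neither that count nor the set tests of the list are therefore independent evidence of its direction. camera with a preset correlation placed the cluster below the other miRNAs (adjusted p = 0.0011), a call lost with an estimated correlation (adjusted p = 0.69 with an estimated correlation).

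Wild type library 1 held the highest value of 3 of the arms, all but miR-222-5p. Without it, miR-221-3p kept a log2 change of -1.90 (limma adjusted p = 0.0060) and miR-221-5p one of -1.47 (limma adjusted p = 0.037). The log2 change of miR-222-3p without that library was -0.74 and did not pass (limma adjusted p = 0.081). The call of miR-221-5p was lost without wild type library 3 or any single knockout library, with limma adjusted p between 0.053 and 0.094, and that of miR-222-5p without any single library, with limma adjusted p between 0.053 and 0.19.

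**Figure D3:**
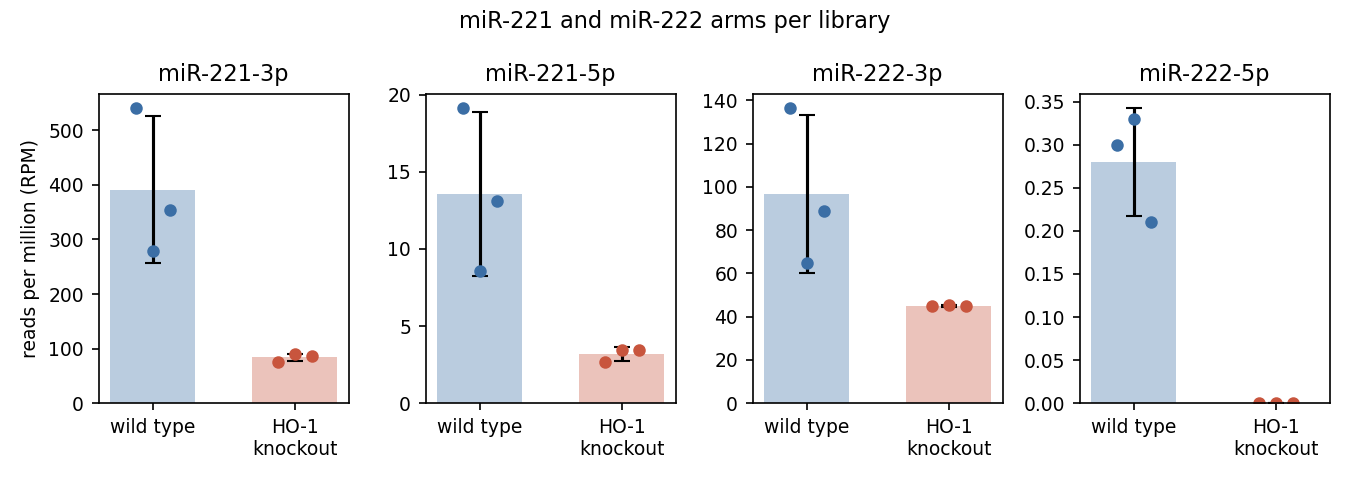
RPM of the 4 arms of miR-221 and miR-222 in each library. Points are libraries, bars are means of 3 libraries from 0, and error bars are SDs. miR-221-3p averages 391 RPM in the wild type and 83.9 RPM in the knockout, and miR-222-5p is at 0 in all 3 knockout libraries.

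The smooth muscle and fibroblast list was fixed as a list of stromal markers, but which cells held its members here was not measured. Of its 19 tested members, 8 fell in the knockout, 0 rose and 11 did not pass, and 12 fell when adjusted over the list alone. miR-143-3p, a smooth muscle miRNA, fell from 11348 ± 2414 to 5914 ± 1034 RPM (SD, n = 3), with a log2 change of -0.93 (SE 0.18, limma adjusted p = 0.025), and miR-125b-5p from 4857 ± 723 to 2545 ± 296 RPM, with a log2 change of -0.93 (SE 0.14, limma adjusted p = 0.015). miR-99a-5p, the most abundant member, stood at 20725.5 ± 3058 and 14826 ± 1124 RPM and did not pass (limma adjusted p = 0.062). The list's median log2 change was -0.88, -0.71 with TMM scaling and -0.65 without wild type library 1, where its members summed to 55099 RPM against 42934 and 46087 RPM in wild type libraries 2 and 3. The call of miR-143-3p was lost without wild type library 1 or 2 or knockout library 1 or 3 (limma adjusted p between 0.071 and 0.13), and that of miR-125b-5p without knockout library 3 (limma adjusted p = 0.071). It was lower than other miRNAs by camera with a preset correlation (adjusted p = 1.1e-05), a call lost with an estimated correlation (adjusted p = 0.69 with an estimated correlation).

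In the endothelial list, 2 of 3 tested members fell. miR-126a-5p went from 983 ± 117 to 573 ± 53 RPM, with a log2 change of -0.77 (SE 0.13, limma adjusted p = 0.016). miR-126a-3p went from 25300 ± 817 to 19302 ± 1170 RPM, with a log2 change of -0.39 (SE 0.08, limma adjusted p = 0.030), and with TMM scaling its change was -0.18 and its call was lost (limma adjusted p = 0.46). In the epithelial miR-200 family, 5 of 9 tested members fell. They were both arms of miR-200a and of miR-200b, and miR-429, which went from 53.3 ± 12.2 to 23.9 ± 2.9 RPM with a log2 change of -1.10 (SE 0.21, limma adjusted p = 0.025). miR-200c-3p, from the other cluster of this family, stood at 46.4 ± 10.4 RPM in the wild type and 58.8 ± 7.5 RPM in the knockout and did not pass (limma adjusted p = 0.36). Neither list passed in camera with a preset correlation (adjusted p = 0.095 for the endothelial and 0.070 for the epithelial list). The epithelial list did pass in camera without wild type library 2 (adjusted p = 0.0029) or knockout library 1 (adjusted p = 0.044), and both lists passed in fry (adjusted p = 0.038 for each). With all 6 libraries, camera gave an adjusted p = 0.69 with an estimated correlation for each of them. fry was run without rescaling, where miRNAs of at least 10 RPM had a median log2 change of -0.29, so a list can pass by sharing that shift. The endothelial median was -0.39, and -0.18 with TMM scaling. The epithelial median was -1.10, and -0.89 with TMM scaling. The call of miR-126a-5p was lost without wild type library 2 or knockout library 1 or 3 (limma adjusted p between 0.058 and 0.085), that of miR-126a-3p without any single library but knockout 2 (0.054 to 0.16), and that of miR-429 without any but wild type 2 (0.063 to 0.13). The call of miR-429 was also lost with upper-quartile scaling. That of miR-200a-5p was lost with RLE and upper-quartile scaling, in the replicate block and with a pseudocount of 5. It was also lost without any single library but wild type 2 (limma adjusted p between 0.089 and 0.18). The call of miR-200b-5p was lost without any single knockout library (limma adjusted p between 0.058 and 0.085). Adjusted over the list alone, 2 endothelial and 5 epithelial members fell. These falls went with the higher share of miR-122-5p in the knockout, 43.4% against 35.2% of the reads.

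**Figure D4:**
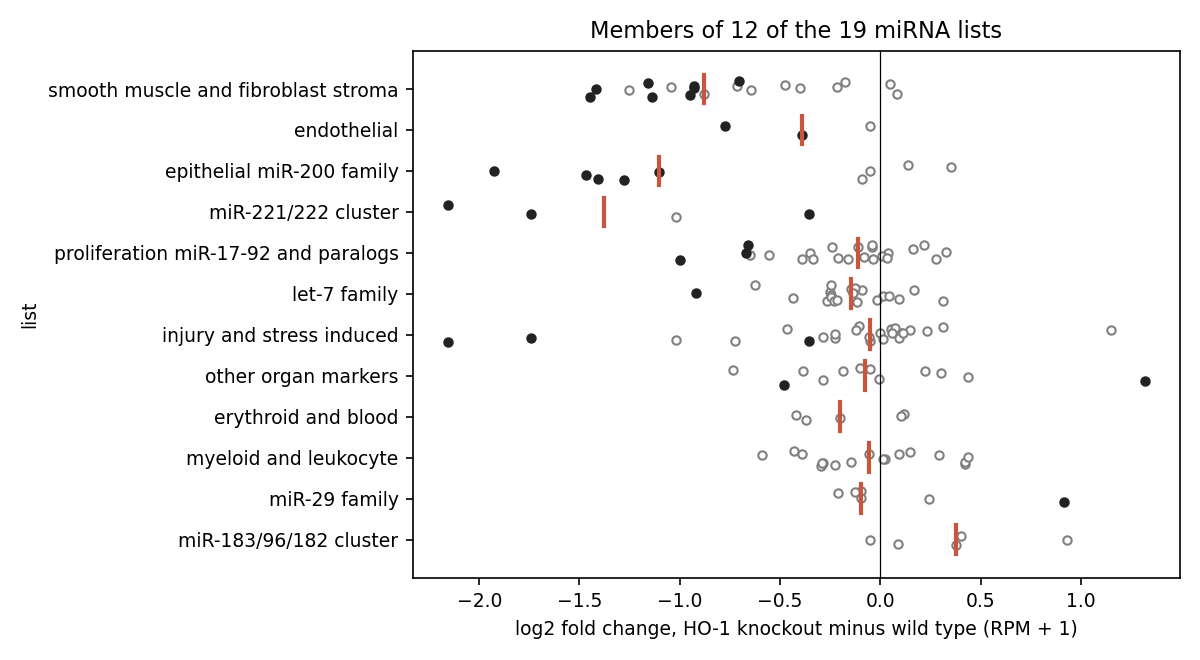
Log2 fold change, HO-1 knockout minus wild type on log2(RPM + 1), of the tested members of 12 of the 19 miRNA lists. Filled points passed a limma adjusted p of 0.05, open points did not, and red bars are list medians, which lie at -0.88 for the stromal list and 0.38 for the cluster of miR-183, miR-96 and miR-182 before any rescaling.

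No leukocyte or red blood cell marker passed the test. None of 17 leukocyte members and none of 5 red blood cell members had a limma adjusted p below 0.05, over all miRNAs or adjusted over the list alone. miR-142-3p stood at 282 ± 23 RPM in the wild type and 378 ± 11 RPM in the knockout (SD, n = 3; limma adjusted p = 0.062), miR-146a-5p at 3259 ± 392 and 2791 ± 381 RPM, and miR-451-5p at 247.7 ± 35.5 and 192.2 ± 30.8 RPM. With TMM scaling miR-142-3p passed, with a log2 change of 0.64 in place of 0.42 (limma adjusted p = 0.019), and miR-146a-5p and miR-451-5p did not. Its other arm, miR-142-5p, passed in no setting. It stood at 328 ± 30 RPM in the wild type and 317 ± 51 RPM in the knockout (limma adjusted p = 0.81). Before any rescaling, 8 of the 9 leukocyte members of at least 10 RPM were lower. Their median log2 change was -0.29, beside -0.29 for all miRNAs of that abundance.

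In the miR-17-92 clusters and their paralogs, which are high in proliferating cells, 3 of 23 tested members fell and 0 rose. miR-20a-5p went from 647 ± 17 to 327 ± 56 RPM, with a log2 change of -0.997 (SE 0.14, limma adjusted p = 0.015), miR-92a-3p from 2939 ± 223 to 1871 ± 274 RPM, and miR-17-5p from 511 ± 57 to 322 ± 42 RPM. The call of miR-92a-3p was lost without wild type library 1 or 2 or knockout library 1 or 3 (limma adjusted p between 0.066 and 0.097), and that of miR-17-5p without any single library (limma adjusted p between 0.062 and 0.097). The call of miR-17-5p was also lost with upper-quartile scaling and in the replicate block. These 3 called members were also the ones that passed adjusted over the list alone, while camera with a preset correlation did not call the list (adjusted p = 0.96). Among 5 tested members of the cluster of miR-183, miR-96 and miR-182, none passed over all miRNAs and 1 rose adjusted over the list alone. That member was miR-183-5p, at 41.0 ± 12.4 RPM in the wild type and 76.8 ± 10.7 RPM in the knockout, beside miR-182 at 116.5 ± 24.7 and 150.6 ± 23.7 RPM and miR-96-5p at 40.6 ± 11.1 and 52.7 ± 4.4 RPM. With TMM scaling miR-183-5p, miR-182 and miR-96-5p each passed over all miRNAs, with log2 changes of 1.14, 0.59 and 0.61 (limma adjusted p = 0.015, 0.031 and 0.047). camera with a preset correlation placed the cluster above other miRNAs (adjusted p = 0.021), a call lost with an estimated correlation (adjusted p = 0.69 with an estimated correlation), in fry (adjusted p = 0.34) and without knockout library 2 (camera adjusted p = 0.076).

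In the miR-29 family, miR-29b-3p rose and 5 other tested members did not pass, among them miR-29a-3p at 4593 ± 228 and 4309 ± 521 RPM. In the let-7 family, 1 of 21 tested members fell, let-7f-2-3p, chosen for naming after its values were seen, and 0 passed adjusted over the list alone. Its call was lost with TMM, RLE and upper-quartile scaling and without any single library (limma adjusted p between 0.065 and 0.19). let-7f-5p stood at 60104 ± 2198 RPM in the wild type and 59331 ± 1175 RPM in the knockout. In the list of markers of other organs, miR-375-3p rose and miR-194-5p fell, the latter from 15124 ± 497 to 10877 ± 1403 RPM, with a log2 change of -0.48 (SE 0.11, limma adjusted p = 0.038) that became -0.27 and lost its call with TMM scaling (limma adjusted p = 0.20), and without any single library but knockout 2 (limma adjusted p between 0.075 and 0.17). Adjusted over the list alone and before any rescaling, miR-375-3p and miR-122-5p rose, and miR-194-5p and miR-192-5p fell. miR-122-3p, the other arm of the miR-122 hairpin, did not pass, at 1420 ± 47 RPM in the wild type and 1326 ± 142 RPM in the knockout. Its log2 change was -0.10 (limma adjusted p = 0.61), and it changed sign in 9 settings. The log2 change of miR-192-5p was -0.29, no larger than the median of -0.29 of miRNAs of at least 10 RPM. The 4 arms of miR-221 and miR-222 belong to the injury list too, and supplied the 3 members of its 25 that fell, while adjusted over the list alone 4 fell, the same 4 arms, and 1 rose. The latter was miR-21-3p, chosen for naming after its values were seen, at 2.12 ± 0.81 RPM in the wild type and 5.77 ± 0.72 RPM in the knockout.

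None of the 2 arms of the hypoxia-induced miR-210 passed over all miRNAs, and 1 fell adjusted over the list alone, miR-210-3p, at 63.6 ± 16.7 RPM in the wild type and 37.7 ± 7.4 RPM in the knockout. None of 7 striated muscle members, of which miR-499-5p was the most abundant at 114.5 ± 31.9 and 71.6 ± 10.4 RPM, and none of 7 members of the pluripotency miR-290 cluster passed either way. The 63 tested members of the imprinted Dlk1-Dio3 cluster did not pass either, with miR-127-3p at 108.4 RPM in wild type library 1 and between 6.45 and 9.81 RPM in the others. camera with a preset correlation called none of the let-7, miR-29, leukocyte, red blood cell, striated muscle, other organ, injury, imprinted, pluripotency, miR-34 and X-linked lists, with adjusted p between 0.34 and 0.96. With 1 library left out, camera called the pluripotency list lower without wild type library 3 (adjusted p = 0.0077) and the imprinted list higher without wild type library 1 (adjusted p = 0.00095). With all 6 libraries, both had an adjusted p = 0.97 with an estimated correlation, which was not run with a library left out.

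The authors' deposited table gave 105 miRNAs with a P-value below 0.05, 50 higher and 55 lower in the knockout. Whether that P-value was adjusted is not known, so this count is not on the threshold of the 36 calls. After Benjamini-Hochberg adjustment of the deposited P-values here, 46 were below 0.05. All 36 miRNAs called here had the same sign in the authors' deposited table, and 34 had a P-value below 0.05 there. For miR-221-3p the authors' deposited table gave a log2 fold change of -2.22 and a P-value of 3.5e-21, and for miR-222-3p -1.10 and 0.00017.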

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

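The block by replicate number was planned, and the quasi-likelihood test, the total without miR-122-5p and the mean of at least 1 RPM were chosen after seeing the data. The 36 calls (4 higher, 32 lower) became 49 (20 and 29) with TMM, 47 (20 and 27) with RLE and 44 (19 and 25) with upper-quartile scaling, 55 (26 and 29) without the 10 most abundant miRNAs in the total and 45 (17 and 28) without miR-122-5p. These scalings moved the median log2 change of miRNAs of at least 10 RPM from -0.29 to between -0.10 and -0.04, which by construction turns calls toward higher, and 27 of the 36 calls remained under TMM, RLE and upper-quartile scaling alike. Calls numbered 50 (9 and 41) at a mean of at least 10 RPM, 49 (8 and 41) at 1 RPM, 46 (7 and 39) and 33 (5 and 28) with pseudocounts of 0.1 and 5, and 15 (2 and 13) with a fold of at least 2. On recovered reads they were 72 (35 and 37) with DESeq2, 62 (30 and 32) with limma-voom, 73 (35 and 38) with edgeR's exact test and 62 (29 and 33) with its quasi-likelihood test. Leaving out 1 library gave 5 to 26 calls, 0 to 8 of them higher and 5 to 22 lower, with fewer samples in each fit. All 36 calls but 4, miR-31a-5p, miR-200b-3p, miR-221-3p and miR-20a-5p, were lost in some of those fits, and these 4 passed under every other setting too, save that miR-20a-5p did not reach a fold of 2.

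With the replicate block, 22 calls (4 and 18) remained, all among the 36. Deviations from the group means of libraries with the same number correlated by 0.03, 0.18 and 0.20 over 218 miRNAs, so the numbers are not treated as pairs. Wild type 1 and its namesake were not each other's best match, while both other numbers were.

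miR-221-3p passed under every setting. The log2 change of miR-221-5p ranged from -2.01 to -1.47 with 1 library left out. That of miR-222-3p ranged from -1.27 to -0.74. It passed at a mean of at least 10 or 1 RPM (-1.02) and with a pseudocount of 0.1 (-1.03). DESeq2 (-0.84), limma-voom (-0.83), edgeR's exact test (-0.87) and its quasi-likelihood test (-0.87) called it too. Adjusted p in these settings lay between 0.0017 and 0.033. It missed with TMM, RLE and upper-quartile scaling, and with totals without miR-122-5p or the 10 most abundant (limma adjusted p between 0.057 and 0.096). The replicate block (0.068) and a pseudocount of 5 (0.077) gave no call either. With 1 library left out it passed only without wild type library 2 (limma adjusted p = 0.035). miR-222-5p no longer passed in the replicate block (-0.35), with a pseudocount of 5 (-0.0785) or with 1 library left out (-0.39 to -0.33). It fell under the filter of limma-voom and both edgeR tests and under a mean of 1 RPM, and DESeq2 gave it an unadjusted p of 0.13 and no adjusted p, so no count test called it. The cause was not tested. camera called 3 lists, and 0 with an estimated correlation. fry called 4, the miR-221/222 and stromal lists of those 3 and also the endothelial and epithelial lists (adjusted p = 0.038 for each), but not the cluster of miR-183, miR-96 and miR-182 (adjusted p = 0.34). The 10 most abundant miRNAs gained 3.38 points of share and the 3 most abundant 7.12.

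No called miRNA among those named changed sign. Of the uncalled ones, let-7f-5p, let-7a-5p, miR-24-3p, miR-25-3p and miR-29a-3p turned from below to above 0. In that order their log2 changes were 0.20, 0.0777, 0.0942, 0.10 and 0.12 with TMM, 0.22, 0.0994, 0.12, 0.13 and 0.14 with RLE, 0.20, 0.0774, 0.0939, 0.10 and 0.12 with upper-quartile scaling, 0.24, 0.12, 0.14, 0.15 and 0.16 without the 10 most abundant, 0.18, 0.0596, 0.0761, 0.0858 and 0.0991 without miR-122-5p, 0.22, 0.0959, 0.12, 0.12 and 0.13 with DESeq2, 0.20, 0.0777, 0.0926, 0.10 and 0.12 with limma-voom, and 0.20, 0.0774, 0.0985, 0.10 and 0.12 with edgeR's exact test and 0.20, 0.0774, 0.0986, 0.10 and 0.12 with its quasi-likelihood test. miR-486 reached 0.011, 0.032, 0.010, 0.052, 0.014 and 0.016 with TMM, RLE, upper-quartile, without the 10 most abundant, DESeq2 and limma-voom. miR-146a-5p reached 0.011 with RLE and 0.030 without the 10 most abundant, where let-7g-5p reached 0.0042. miR-202-5p fell to -0.0443 with a pseudocount of 0.1. These are shifts of the zero point except for miR-202-5p, which lies near 1 RPM.

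The values above understate how often uncalled miRNAs changed sign. The rule fixed beforehand allows 80 miRNAs. Among them, 21 uncalled list members were left out of the named set only after their sign changes had been seen. Of these, 16 changed sign in some setting, in 85 of the 149 sign changes under the full rule, and 0 passed the threshold in any setting. They were let-7c-5p, miR-1-3p, miR-10a-5p, miR-122-3p, miR-133a-3p, miR-142-5p, miR-144-3p, miR-183-3p, miR-27a-3p, miR-292-3p, miR-29c-3p, miR-29c-5p, miR-34b-3p, miR-411-5p, miR-541-5p and miR-741-3p. Of the called miRNAs, 0 changed sign under the full rule.

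With 1 library left out, log2 changes ranged from -0.17 to 0.0028 for miR-29a-3p, -0.18 to 0.33 for miR-34a-5p, -0.27 to 0.19 for miR-202-5p, -0.0407 to 0.0106 for let-7f-5p, -0.0794 to 0.15 for miR-210-5p and -1.21 to 0.32 for miR-379-5p. Without wild type library 1 the imprinted Dlk1-Dio3 cluster turned upward in camera (adjusted p = 0.00095, against 0.15 to 0.99 without any other library). camera also called the pluripotency list without wild type library 3 (adjusted p = 0.0077) and the epithelial list without wild type library 2 (adjusted p = 0.0029) or knockout library 1 (adjusted p = 0.044), and lost the cluster of miR-183, miR-96 and miR-182 without knockout library 2 (adjusted p = 0.076). Of the other results, 81 values for named miRNAs lost their call, 66 gained one and 859 kept both direction and side. The depth of 8300536 to 10042673 reads limits calls of miRNAs near 0.299 to 0.361 RPM, the floor of 3 reads.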

Other observations

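The calls in this part are those of limma's test, fixed beforehand, while the tests of the 3 patterns, the random draws and the count of other splits were chosen only after the results they bear on were seen. Some called miRNAs lay beside each other in the genome. In the RefSeq table on GRCr8, 6 groups of precursors less than 10000 bp apart held called arms of 2 or more precursors, a count of 0 to 3 with 1 library left out. These were miR-17, miR-20a and miR-92a, then miR-143 and miR-145, miR-200a, miR-200b and miR-429, miR-221 and miR-222, miR-322 and miR-542, and a second copy of miR-17 and miR-92a, whose mature reads cannot be assigned to either copy. The 16 arms called in these 6 groups all fell in the knockout, out of 43 tested, as did 32 of all 36 calls. Of the 22 arms of at least 10 RPM, 10 were not called, and 3 of those had log2 changes above 0 before any rescaling, miR-145-3p at 0.081, miR-19a-3p at 0.22 and miR-363-3p at 0.33. In the miR-200 family the fall was in the group of miR-200a, miR-200b and miR-429, while miR-200c-3p, which lies elsewhere, was at 46.4 RPM in the wild type and 58.8 RPM in the knockout.

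Wild type library 1 stood apart in miRNAs of the imprinted Dlk1-Dio3 cluster, whose summed value was 251 RPM there and between 22.49 and 34.99 RPM in the other 5 libraries. miR-10b-5p, chosen after its values were seen, was at 332 RPM there and between 72.0 and 110.0 RPM elsewhere, and miR-199a-3p at 3513 RPM against 655 to 1648 RPM.

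The first pattern is that miR-122-5p held between 32.7% and 46.4% of the reads in the libraries labelled testis. Liver as the source of the sequenced RNA and liver RNA mixed into testis RNA both stay open. Loss of germ cells with Sertoli cells remaining could lower germ cell miRNAs, but names no source for miR-122-5p. A share of at least 32.7% of this hepatocyte miRNA in every library argues against that loss as the sole explanation. Whether germ cells were lost as well cannot be told here. Of the organ markers fixed beforehand only those of miR-122, miR-192 and miR-194 were abundant, and the highest mean of any other was 77.592 RPM, for miR-375-3p, which does not separate liver from a mixture. miR-202-5p reached 2.22 RPM and the summed testis miRNAs 57.56 RPM (41.2 to 57.56 RPM in the wild type, 29.39 to 34.65 RPM in the knockout). No testis library of known level was at hand to set the levels that a mixture or a loss of germ cells would give. All 6 libraries share the profile, so it is not a swap between genotypes.

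The second pattern is that 32 of the 36 calls were lower in the knockout. The higher share of miR-122-5p lowers every other RPM value, yet 28 of the 32 lower calls remained when it was left out of the total, which argues against it as the cause of those calls. Whether it is the cause of the excess of lower calls stays open, because the move of the median log2 change of miRNAs of at least 10 RPM from -0.29 to -0.09768, and with it of higher calls from 4 to 17, is set by its shares once it is left out. The excess itself depended on the scaling. TMM scaling gave 20 higher and 29 lower calls, and DESeq2 on recovered reads gave 35 and 37. A lower share of every cell type other than the one that holds miR-122 would lower stromal and leukocyte markers alike. That holds only if each list marks its cell type alone. The stromal score fell by 0.5657 more on the log2 scale than the leukocyte score (SE 0.13, and by 0.45 without wild type library 1). The exact two-sided permutation p of that gap was 0.1, the smallest possible. Which cells held these miRNAs was not measured, so the gap does not exclude such a lower share. An effect of the HO-1 genotype on stromal, endothelial or epithelial miRNAs, or on how much of each cell type the samples held, stays open and was not tested.

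The third pattern is the grouping of calls in precursor clusters. Random draws of as many tested miRNAs of similar abundance gave a median of 2 such groups, and 26 of 2000 draws gave 6 or more. This excess did not hold in most other settings, since under 5% of draws were as large in 1 of 21, a mean of at least 10 RPM (8 groups, 40 of 1000 draws), against 195 of 1000 with TMM scaling (6 groups) and 157 of 1000 with edgeR's quasi-likelihood test (8 groups). The second precursor of 3 groups rests on miR-17-5p, miR-222-5p or miR-542-3p, whose calls were each lost without any single library. Shared primary transcripts, cell types that express whole clusters and no grouping beyond chance cannot be told apart by the count of 6 groups.

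Of the 10 splits of the 6 libraries into 3 against 3, 1 gave as many calls as the real split, which was the real one with 36, and the highest of the others was 0. With 10 splits the share cannot go under 0.05.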
